A study of Rattus norvegicus with 8 samples.

How the data were processed

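GH3 cells, a rat pituitary tumour line that makes growth hormone, were profiled by m6A methylated RNA immunoprecipitation and sequencing. Per the labels, RNA was fragmented, incubated with an m6A antibody and made into libraries with a dUTP second strand, which marks strand. The labels list 8 libraries in 4 groups of 2: control input, shFTO input, control immunoprecipitate and shFTO immunoprecipitate. A tag in each title ties an input to the immunoprecipitate of the same RNA sample. Groups and replicate numbers were taken from the titles. The labels do not state that replicates came from separate cultures, so a p-value that compares libraries measures only the spread between these samples. That spread may be technical. The p-values of camera at its preset correlation, of permuted peak labels and of Fisher's exact test compare genes with other genes, not samples.

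The deposited gene table holds counts for 17883 gene symbols in 4 columns that carry the RNA sample tags. The authors' values were taken to be expected counts, because 268 of the 71532 values, in 108 symbols, were not whole; the counts were rounded to whole numbers, which touched 47 tested genes. The columns were read as the input libraries because the table is called an expression count. Neither the column names nor the labels say whether input or immunoprecipitate was counted, and this reading limits every expression result. STAR, featureCounts and MACS2 are named without roles or versions per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands, near-identical paralogs and pseudogene families remain uncertain.

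The deposited peak table is 1 merged list, not a list per sample, and gives for each peak a gene, a location class and a value per RNA sample. No unit is given per the file headers; the authors' peak values were read as a linear ratio of immunoprecipitate over input. They are positive, and across peaks their Spearman correlation with the gene count was -0.115 in control replicate 1, which is unlike coverage that grows with expression. How the ratios were scaled between libraries is not given in the sources used here. The deposited log2 fold change equals log2 of the mean shFTO ratio over the mean control ratio, with a largest difference of 5.3e-15. The deposited p-value takes its smallest value, 0.333, wherever the genotypes do not overlap, as an exact rank test on 2 against 2 would. Peak coordinates are printed as the authors gave them, with build and counting base not given in the sources used here, and widths are end minus start.

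Expression was compared between the 2 shFTO and 2 control input columns with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) after TMM scaling and filterByExpr, which left 13043 genes with 99.9% of the counts. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors were derived from the F statistic, and CPM values are library-scaled counts (edgeR, TMM) with the SD between replicates. The 23 gene lists and the markers of other cell types were fixed before the data were examined, as were the tests, the samples in each fit, the named-gene rule and most of the other settings. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 23 lists. Camera with an estimated correlation and fry were run beside it, and members were also counted with p-values adjusted over the list alone.

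Genes named in the text follow a rule: Fto first, then the 12 genes with the largest log2 fold change in each direction. These had to pass the test, keep both libraries of a genotype above both of the other, average at least 5 CPM in the higher group and carry an established symbol. The rule adds Gh1, Prl, Pou1f1, Alkbh5, Mettl3, Mettl14 and Wtap, and up to 4 members of each list with the smallest p. Since no peak passed, the 5 peaks per direction with the smallest limma p in genes with an established symbol are named instead. Single members that moved against their list, and further members or genes named beyond this rule, were chosen after their values were seen. Not every list member under the rule is printed: those whose call held without each library were preferred, a choice also made after the values were seen.

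Peak ratios were tested with limma (trend) on log2 values, 2 against 2, a test added after the data were examined because the deposited p-value cannot fall below 0.333. Genes with a peak were compared with other tested genes by the difference of median log2 fold change, weighted over 20 bins of mean expression, with labels permuted 10000 times within bins. A first form of this estimator recovered too small a share of a simulated shift and was replaced; it had given the same direction on the deposited data. Genomic spans and gene symbols came from a RefSeq table of assembly GRCr8, used for no coordinate, and 11543 tested genes matched (88.5%). Shares of list genes with a peak were compared by Fisher's exact test with adjustment over the lists, a test chosen after the shares were seen. Intervals of single shares are exact Clopper-Pearson intervals at 95%, and they and the floor of 3 counts cover counting error only.

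The tests of genes, of peak ratios and of the matched difference were run on simulated data. For shFTO against control input, with 200 of 12913 genes changed, edgeR called 176 genes, 7 of them falsely, recovering 74% of 1.5-fold and 95% of 3-fold changes, while DESeq2 called 159. Genes were drawn independently and with the same spread in both genotypes. The deposited control pair varied more than the shFTO pair, so these shares need not hold for the deposited counts. For peak ratios, with 200 of 11969 changed, limma called 91, 3 of them falsely, recovering 17% of 2-fold and 71% of 4-fold changes. The matched difference recovered a shift of -0.1 as -0.0994 ± 0.0127 (SD), and 3 of 100 runs without a shift gave a p under 0.05. Camera was simulated only with genes that vary independently, where 4 of 100 lists without a change had a p under 0.05, which says nothing about correlated genes. The fry and Fisher tests were not simulated. Column totals ran from 17805265 to 18511206 counts, so 3 counts correspond to 0.162 to 0.168 CPM.

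Alternatives covered size-factor (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter, a minimum of 10 counts, a minimum fold of 1.5, the replicate number as a block and the omission of each library. Where a library is left out, the lone library of its genotype is assumed to vary like the other genotype. Relative to counting error, the control pair varied more than the shFTO pair (chi-square over degrees of freedom 7.28 and 3.33). A call lost without an shFTO library can therefore reflect the control spread and need not mean that the effect rests on that library. For peaks, they covered stricter thresholds, a fold of at least 2 and ratios of at least 1. Comparisons of immunoprecipitate with input per gene, their change between genotypes and the fit over all 8 libraries were not run, because gene counts of the immunoprecipitates were not used here. The DRACH motif was not searched because no genome sequence was used here, and an overlap minimum between peak sets had no application to a merged list.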

Results

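The study asked how lowering FTO, an enzyme that removes m6A from RNA, alters gene expression and m6A in GH3 cells. Short hairpin RNA against FTO (shFTO) was compared with control in 2 replicates per genotype. Each replicate was sequenced as input RNA and as m6A immunoprecipitate. Gene counts, read as input, totalled 17911384 and 17805265 in control replicates 1 and 2 and 18511206 and 17879888 in shFTO replicates 1 and 2. Between 15829 and 16184 gene symbols had a count in a library. The peak table listed 11969 m6A peaks, each with a ratio per RNA sample, read as immunoprecipitate over input.

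Fto, the targeted gene, stood at 190.2 and 179 CPM in control replicates 1 and 2 and at 50.0 and 59.0 CPM in shFTO replicates 1 and 2. The mean fell from 185 ± 8.03 to 54.5 ± 6.31 CPM (SD, n = 2 per genotype), 29.5% of control, with a log2 fold change of −1.75 ± 0.087 (SE, edgeR adjusted p = 2.18e-07). Alkbh5, the other m6A eraser, also fell (−0.37 ± 0.073, edgeR adjusted p = 0.00358). The writer subunit genes Mettl3 (0.35 ± 0.078, edgeR adjusted p = 0.00737) and Wtap (0.30 ± 0.065, edgeR adjusted p = 0.00692) rose. Mettl14, the partner of Mettl3, had a log2 fold change of 0.14 ± 0.082 and did not pass (edgeR adjusted p = 0.236). Without shFTO replicate 1 the calls of Mettl3 and Wtap were lost, though their log2 fold changes were 0.34 and 0.28. The call of Wtap was also lost without shFTO replicate 2, at a log2 fold change of 0.31. Mettl14 passed without control replicate 1 (edgeR adjusted p = 0.0437, log2 fold change 0.22) and stood at 0.06 without control replicate 2. Over all 12 alternatives the adjusted p ranged from 6.38e-06 to 1 for Mettl3, from 1.95e-06 to 1 for Wtap and from 0.0437 to 1 for Mettl14, the value of 1 coming from the test against a fold of 1.5. Of the 27 tested m6A writers, erasers and readers, 3 rose and 3 fell, both over all genes and adjusted over the list alone, and the list did not move as a set (median log2 fold change 0.004, and 0.064 without shFTO replicate 1, 0.030 without control replicate 1 and 0.012 without shFTO replicate 2; mean −0.01; camera adjusted p = 0.875). Besides Fto and Alkbh5, the reader gene Prrc2a fell (−0.31 ± 0.060, edgeR adjusted p = 0.00284), a call lost without shFTO replicate 1 (0.0790) or 2 (0.0550) within a range of 2.98e-09 to 1 over the 12 alternatives. None of the list was called higher without shFTO replicate 1, and without control replicate 1 there were 5 higher and 5 lower.

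**Figure D1:**
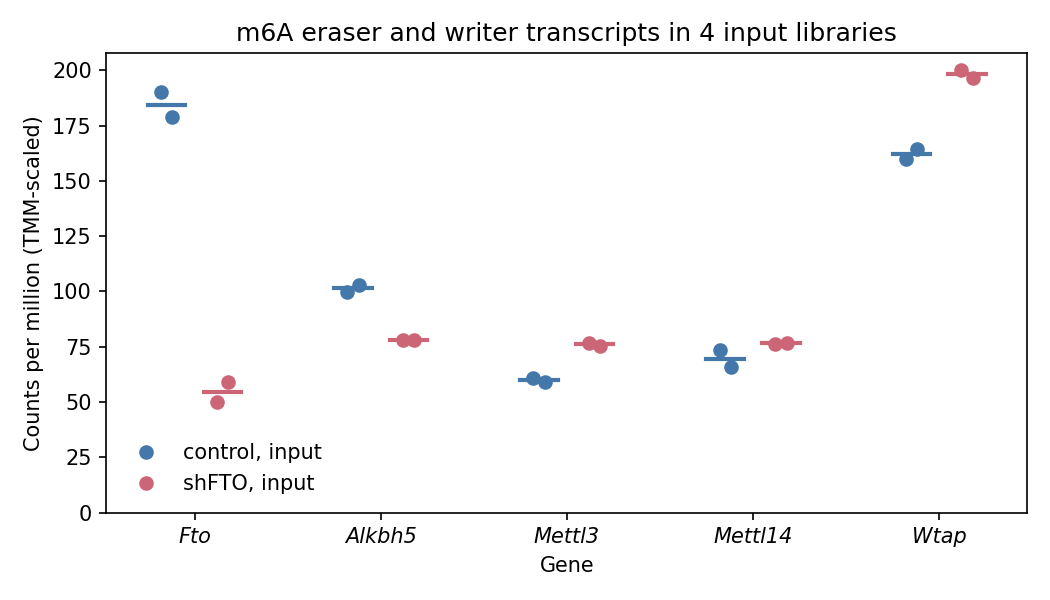
TMM-scaled CPM of m6A eraser and writer genes in the control and shFTO input libraries, with points for single libraries and bars for the mean of 2 replicates. Fto lies between 50.0 and 59.0 CPM in both shFTO libraries and at 178.8 CPM or more in both control libraries.

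Among 13043 tested genes, 1327 rose and 1535 fell in shFTO input, 21.9% of those tested. The changes were mostly small, with a median fold of 1.35 among the 2862 calls, and 150 genes rose and 130 fell at least 2-fold. The largest rises included Atp6v1g3, a subunit of the vacuolar proton pump, from 24.1 ± 1.04 to 101 ± 2.46 CPM (log2 fold change 2.07 ± 0.086, edgeR adjusted p = 1.03e-07). Arpc3, a subunit of the actin-nucleating Arp complex, went from 101 ± 6.12 to 280.1 ± 0.196 CPM (1.48 ± 0.070, edgeR adjusted p = 2.03e-07). The matrix genes Col11a1, a fibrillar collagen chain, and Dcn, the proteoglycan decorin, rose by log2 fold changes of 2.21 ± 0.32 and 1.85 ± 0.13 (edgeR adjusted p = 0.000484 and 2.54e-06). Herc6 (2.11), Tktl1 (1.62), the keratin gene Krt75 (1.62), Mrps36 (1.49), Lmo3 (1.37), the transcription factor gene Runx2 (1.36), Dnai1, an axonemal dynein chain (1.30), and the endothelin receptor gene Ednra (1.30) completed the 12 largest under the naming rule. That rule leaves out genes under 5 CPM in the higher group, such as Vim (4.86) and Ptprc (3.01), and genes without an established symbol. The log2 fold change of Dnai1 was 0.77 without control replicate 1 and 2.16 without control replicate 2. DESeq2 did not call Dnai1 (adjusted p = 0.194, with a range of 9.48e-14 to 0.339 over the 12 alternatives).

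The largest falls included Angpt2, which encodes the secreted vascular ligand angiopoietin, from 43.7 ± 0.0070 to 10.99 ± 0.271 CPM (log2 fold change −1.98 ± 0.11, edgeR adjusted p = 5.61e-07). Sez6, a neuronal membrane protein gene, fell from 82.5 ± 7.91 to 26.4 ± 1.03 CPM (−1.63 ± 0.096, edgeR adjusted p = 9.42e-07). The phospholipase gene Pla2g4d (−2.33 ± 0.16), the metabotropic glutamate receptor gene Grm4 (−2.24 ± 0.28) and the neural matrix gene Tnr (−2.08 ± 0.24) had the largest falls under the naming rule (edgeR adjusted p = 2.54e-06, 0.000171 and 9.08e-05). Golga7b (−1.95), Lhfpl5 (−1.84), Tcf15 (−1.83), Fto itself (−1.75), the vesicle fusion gene Napb (−1.71), the Wnt antagonist receptor gene Kremen1 (−1.65) and the Notch-modifying glycosyltransferase gene Mfng (−1.62) were the others among the 12. At an unadjusted p under 0.05 there were 4646 genes. The count of calls fell to 1430 without shFTO replicate 1 and to 1682 without shFTO replicate 2, and was 3835 and 3714 without control replicates 1 and 2. Higher genes made up 46.4% of calls with TMM scaling and 54.4% with upper-quartile scaling.

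Growth hormone itself, Gh1, rose from 7269 ± 547 to 9377 ± 364 CPM (log2 fold change 0.37 ± 0.066, edgeR adjusted p = 0.00185), and Pou1f1, the pituitary lineage factor that drives it, rose by 0.38 ± 0.059 (edgeR adjusted p = 0.000884). Against these, 8 of the 19 tested pituitary hormone and lineage genes fell. They included the secretory granule genes Chgb (−0.97 ± 0.058) and Chga (−0.81 ± 0.071), the somatostatin receptor gene Sstr1 (−0.69 ± 0.075) and the thyrotropin-releasing hormone receptor gene Trhr (−1.49 ± 0.18), with edgeR adjusted p from 9.42e-07 for Chgb to 0.000121 for Trhr. Prl, which encodes prolactin, had 1 and 0 counts in control and 2 and 0 in shFTO and was not tested. GH3 is a somatolactotroph line, of the lineage that makes growth hormone and prolactin, so counts this low are unexpected. Whether Prl was silent in these cells or its reads were not counted cannot be told from the counts. Adjusted over the list alone, 2 rose and 9 fell. The list median was −0.23 (camera adjusted p = 0.0127; adjusted p = 0.421 with an estimated correlation, in a range of 0.00817 to 0.421 over 7 alternatives). Without control replicate 2 the list call was lost (camera adjusted p = 0.0600, median −0.11), and without shFTO replicate 1 that of Gh1 (edgeR adjusted p = 0.0701, in a range of 2.79e-19 to 1 over 12 alternatives).

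All 13 mitochondrially encoded protein genes rose, also when adjusted over the list alone, with a median log2 fold change of 0.56 (camera adjusted p = 1.08e-07; adjusted p = 0.421 with an estimated correlation, the smallest of 7 alternatives being 7.46e-08). Mt-atp8 and Mt-nd6, subunits of ATP synthase and complex I, rose by 0.97 ± 0.076 and 0.90 ± 0.069 (edgeR adjusted p = 6.28e-06 and 5.1e-06). Without shFTO replicate 1 or 2, 12 of the 13 were called. The exception without shFTO replicate 2 was Mt-co1 (edgeR adjusted p = 0.170). These genes took 4.98% and 4.83% of counts in control and 6.48% and 6.52% in shFTO (exact permutation p = 0.333, two-sided, the smallest that 2 against 2 can give). Of 23 tested cholesterol synthesis genes, 14 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 3.54e-05; adjusted p = 0.421 with an estimated correlation, the smallest of 7 alternatives being 3.08e-05). Insig1, a regulator of sterol sensing, rose by 1.03 ± 0.078, and the synthesis enzyme genes Hmgcs1, Msmo1 and Fdps rose by 0.79 ± 0.067, 0.80 ± 0.071 and 0.70 ± 0.062 (edgeR adjusted p from 4.39e-06 to 1.44e-05).

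Among 29 tested cytoplasmic ribosomal protein genes, 14 rose and Rpl13a fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 3.54e-05; adjusted p = 0.649 with an estimated correlation, the smallest of 7 alternatives being 2.73e-05). Rpl23 (0.41 ± 0.059), Rps3 (0.40 ± 0.061) and Rpl7 (0.38 ± 0.061) rose and Rpl13a changed by −0.48 ± 0.071 (edgeR adjusted p from 0.000503 to 0.000976). Ribosomal protein genes have many near-identical pseudogenes, so how reads were shared among copies remains uncertain, and without shFTO replicates 1 and 2 only 5 and 7 were called higher, against 22 without control replicate 1. In the list of the unfolded protein and integrated stress response, 10 of 29 rose and 1 fell (11 and 1 adjusted over the list alone). The chaperone gene Hspa5 rose by 0.49 ± 0.070, Chac1, a glutathione-degrading enzyme gene, by 0.82 ± 0.095, and the oxidoreductase gene Ero1b by 0.74 ± 0.13 (edgeR adjusted p = 0.0005, 9.95e-05 and 0.00194). The median was 0.16 (camera adjusted p = 0.00315; adjusted p = 0.421 with an estimated correlation, the smallest of 7 alternatives being 0.00238). Without shFTO replicate 1 the median was 0.10 with 4 genes called higher, without shFTO replicate 2 there were 5, and without control replicate 2 there were 17. Of 24 tested interferon response genes, 5 rose and Ddx58 fell (6 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00353; adjusted p = 0.421 with an estimated correlation, the smallest of 7 alternatives being 0.0015). The immunoproteasome gene Psmb9 rose by 0.61 ± 0.095 (edgeR adjusted p = 0.000885). Oas1a had 4 counts in control and 29 in shFTO, a ratio of 7.12 with an exact 95% counting interval of 2.5 to 27.9. Its call was lost without control replicate 1 (edgeR adjusted p = 0.0761) or shFTO replicate 1 (0.108), in a range of 0.00157 to 0.198 over 11 alternatives, and that of Ddx58 without shFTO replicate 1 (0.287). Only 1 interferon gene was called higher without shFTO replicate 1; without shFTO replicate 2 there were 2, without control replicate 1 there were 3, and without control replicate 2 there were 8.

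Ion channel and excitability genes were lower as a group: 13 of 22 fell and Syt1 rose (15 and 2 adjusted over the list alone), with a median log2 fold change of −0.34 (camera adjusted p = 0.000217; adjusted p = 0.421 with an estimated correlation, the smallest of 7 alternatives being 4.84e-05). The calcium channel gene Cacna1g fell from 320 ± 33.5 to 131 ± 3.20 CPM (−1.28 ± 0.079, edgeR adjusted p = 9.73e-07). The potassium channel gene Kcnh2 fell by 0.68 ± 0.068 and the pacemaker channel gene Hcn2 by 0.89 ± 0.081 (edgeR adjusted p = 3.27e-05 and 1.64e-05). Syt1, a synaptic vesicle gene, stood at 0.39 ± 0.11 (edgeR adjusted p = 0.0246), a call lost without shFTO replicate 2 (0.162). In the cAMP/PKA list, 9 of 25 genes fell and 0 rose at the edgeR threshold, also when adjusted over the list alone, with a median of −0.18 (camera adjusted p = 0.0095; adjusted p = 0.421 with an estimated correlation, the smallest of 7 alternatives being 0.00878). Pde3a, a cyclic nucleotide phosphodiesterase gene, changed by −0.97 ± 0.092 and the adenylyl cyclase gene Adcy6 by −0.71 ± 0.070 (edgeR adjusted p = 2.13e-05 and 3.12e-05). Without shFTO replicates 1 and 2, 5 and 4 genes of this list were called lower.

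In the G1/S and DNA replication list, 5 of 27 fell and Ccnd3, a D-type cyclin gene, rose by 0.41 ± 0.071 (edgeR adjusted p = 0.00157), with the same counts adjusted over the list alone. Uhrf1, a factor that maintains DNA methylation, changed by −0.76 ± 0.085, and E2f2 and Cdk6 by −0.77 ± 0.14 and −0.59 ± 0.12 (edgeR adjusted p = 8.56e-05, 0.00203 and 0.00467). The list median was −0.18 (camera adjusted p = 0.0149; adjusted p = 0.840 with an estimated correlation, in a range of 5.2e-06 to 0.840 over 7 alternatives). The controls differed here: without control replicate 1 the median was −0.0059 (camera adjusted p = 0.729) with 5 genes lower and 3 higher, and without control replicate 2 it was −0.37 with 22 genes lower. The G2/M and mitosis list behaved likewise. It did not pass with all libraries (3 of 29 lower, 0 higher at the edgeR threshold, also adjusted over the list alone, median −0.12, camera adjusted p = 0.151). Its median changed sign with the controls, 0.08 without control replicate 1 and −0.22 without control replicate 2 (camera adjusted p = 3.5e-05 with 16 genes lower), was −0.07 without shFTO replicate 2, and its adjusted p reached 0.849 over 7 alternatives. Of 19 cell adhesion and junction genes, 7 fell (7 lower and 1 higher adjusted over the list alone), among them the laminin receptor gene Itga6 (−0.75 ± 0.087) and the plakoglobin gene Jup (−0.41 ± 0.063), with edgeR adjusted p = 0.000101 and 0.000707. The list median was −0.11 (camera adjusted p = 0.0196; adjusted p = 0.481 with an estimated correlation, in a range of 0.0343 to 0.481 over 7 alternatives). Its call was lost without control replicate 2 (0.0632), shFTO replicate 1 (0.0589) or shFTO replicate 2 (0.0529), where 3 genes were called lower without either shFTO replicate.

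**Figure D2:**
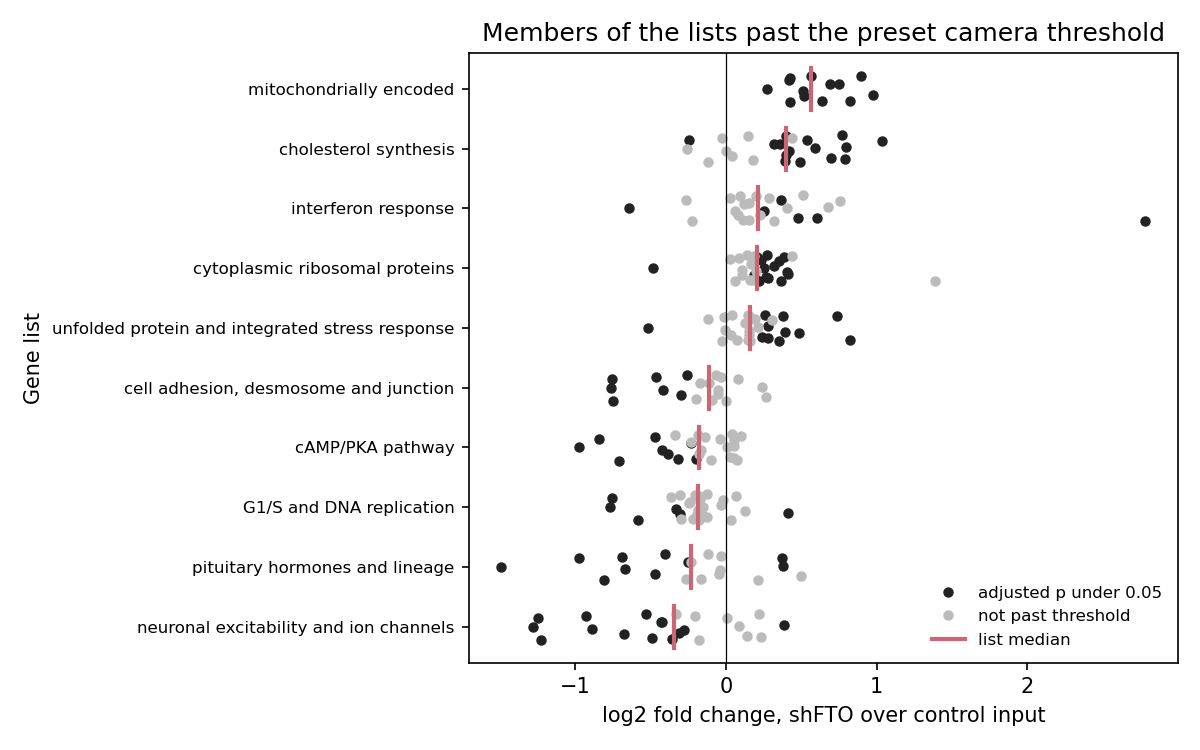
Log2 fold change (shFTO over control input) of every tested member of the 10 gene lists past the preset camera threshold, with black points for members past the edgeR threshold, grey points for the others and a red line at each list median. All 13 mitochondrially encoded genes lie above 0 and the ion channel median lies at −0.34.

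The other lists did not pass camera. Immediate early genes had 4 of 28 higher and 1 lower, also adjusted over the list alone (median 0.04, and 0.061, 0.073 and 0.080 without control replicate 2, shFTO replicate 1 and shFTO replicate 2; camera adjusted p = 0.656); Myc, a growth regulator, rose by 0.96 ± 0.11 and Fosl2 changed by −0.46 ± 0.076 (edgeR adjusted p = 0.000106 and 0.00123). Of 31 transcripts widely reported to carry m6A, 2 rose and 8 fell (4 and 10 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.0622). This list passed without control replicate 1 (0.0229) and without shFTO replicate 2 (0.0228), its median was −0.09 without control replicate 2, and its adjusted p reached 0.649 over 7 alternatives from a smallest value of 0.0213. Mycn rose by 0.59 ± 0.070 and the chromatin remodelling gene Arid1a changed by −0.44 ± 0.069 (edgeR adjusted p = 0.000122 and 0.000964). Wnt and Notch genes had 1 of 19 higher and 4 lower, also adjusted over the list alone, with Wnt10a at −0.63 ± 0.096 and the Notch ligand gene Jag2 at −0.44 ± 0.066 (edgeR adjusted p = 0.000758 and 0.000628). Their median was −0.16 (camera adjusted p = 0.0630, and 0.421 with an estimated correlation). The Wnt and Notch list passed without control replicate 2, with a median of −0.27, and without shFTO replicate 2, with a median of −0.22. Insulin, IGF and mTOR genes had 3 of 25 higher and 6 lower (3 and 9 adjusted over the list alone), with the mTOR complex gene Rptor at −0.45 ± 0.076 and Igfbp4 at −0.63 ± 0.12 (edgeR adjusted p = 0.00131 and 0.00319). Their median was −0.18 (camera adjusted p = 0.102, in a range of 0.0343 without control replicate 1 to 0.673 over 7 alternatives; 0.0383 without shFTO replicate 2), and −0.07 and −0.09 without control replicate 2 and shFTO replicate 1. The number of called members depended on the library left out. In each list of this paragraph it fell without shFTO replicate 1 and rose without control replicate 2.

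Lipid genes had 5 of 26 higher and 4 lower (6 and 6 adjusted over the list alone), with opposite members among the strongest. Plin2, a lipid droplet coat gene, rose by 0.94 ± 0.068 and the fatty acid oxidation gene Acadm by 0.57 ± 0.089, while Cpt1a, which carries fatty acids into mitochondria, changed by −0.63 ± 0.076 (edgeR adjusted p from 3.14e-06 to 0.000844). Their median was −0.03 and their mean 0.0019 (camera adjusted p = 0.852). Glycolysis and hypoxia genes had 4 of 25 higher and 2 lower (5 and 3 adjusted over the list alone), including Pgam1, a glycolytic mutase gene, at 0.70 ± 0.060 and the hexokinase gene Hk1 at −0.57 ± 0.071 (edgeR adjusted p = 1.15e-05 and 0.000171; list median 0.05, camera adjusted p = 0.728). In the p53 target list 4 of 18 rose and 2 fell (5 and 3 adjusted over the list alone), with Gadd45a at 0.39 ± 0.093 (edgeR adjusted p = 0.0108; list median 0.16, camera adjusted p = 0.376). Apoptosis regulators had 3 of 21 higher and 3 lower (5 and 3 adjusted over the list alone), with the pro-apoptotic gene Bik at 0.74 ± 0.094 (edgeR adjusted p = 0.000213; list median 0.01, camera adjusted p = 0.806). Of 11 immune mediators 4 rose and 1 fell, also adjusted over the list alone, including the class I antigen gene B2m at 0.44 ± 0.067 and Tlr3, a receptor for double-stranded RNA, at 0.90 ± 0.15 (edgeR adjusted p = 0.000778 and 0.00112). Their median was −0.06, their mean 0.27 and the direction of the test upward (camera adjusted p = 0.788). Matrix and invasion genes had 2 of 13 higher and 2 lower (3 and 3 adjusted over the list alone), with the receptor gene Tgfbr2 at −0.53 ± 0.089 (edgeR adjusted p = 0.00135). Their median was −0.04 and their mean 0.22 (camera adjusted p = 0.852). Without shFTO replicate 1 the number of called members fell in each of these lists. Without control replicate 2 it rose for lipid, glycolysis and hypoxia, p53 target and apoptosis genes and stayed the same for immune and matrix genes. Several medians near 0 depended on a library. That of apoptosis genes was −0.064 without control replicate 1, −0.0070 without shFTO replicate 2 and 0.036 without shFTO replicate 1, and that of matrix genes 0.12 without control replicate 2. The immune median was −0.11 without control replicate 1, −0.10 without shFTO replicate 1 and −0.11 without shFTO replicate 2. The lipid median was −0.081 and −0.015 without control replicates 1 and 2, and the glycolysis median 0.018 and 0.083 without shFTO replicates 1 and 2. Of 5 tested neighbours of Fto only Chd9 passed (−0.43 ± 0.078, edgeR adjusted p = 0.00223, and 0.0573 without shFTO replicate 1, in a range of 2.89e-11 to 1 over 12 alternatives). The neighbour list had a median of −0.02 that was 0.01 with upper-quartile scaling and ran from −0.066 (without shFTO replicate 1) to −0.0058 (without control replicate 2) with a library left out (camera adjusted p = 0.728). With an estimated correlation 0 of the 23 lists passed (smallest camera adjusted p = 0.421), against 10 with the preset value and 7 by fry, which asks only whether members move one way. The estimate lay below the preset 0.01 for cholesterol synthesis (−0.010), cAMP/PKA (−0.039) and pituitary genes (−0.026), so correlated members do not explain those losses. For the other lists past the preset value it was above 0.01, up to 0.696 for G1/S genes. Camera with an estimated correlation takes its degrees of freedom from the 4 libraries, so its failures decide little. Fry tests against the spread between libraries, and not every list past the preset camera threshold passed it. The G1/S (fry adjusted p = 0.391), interferon (0.0556), unfolded protein (0.0556) and ribosomal protein lists (0.0896) did not pass fry. The Wnt and Notch list, which did not pass camera, passed fry (fry adjusted p = 0.0455).

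Markers of other cell types moved in both directions. The leukocyte gene Ptprc had 9 and 13 counts in control and 86 and 93 in shFTO (log2 fold change 3.01 ± 0.32, edgeR adjusted p = 4.96e-05), the stem cell enzyme gene Aldh1a1 8 and 17 against 66 and 82 (2.56 ± 0.36, edgeR adjusted p = 0.000446) and the fibroblast gene Dcn 132 and 156 against 517 and 517. The complement gene C1qa, also a macrophage marker, had 15 and 15 counts in control and 0 and 0 in shFTO, at least 10.2-fold lower with a floor of 3 counts over the group, and the neuronal gene Gad1 changed by −0.46 ± 0.092 (edgeR adjusted p = 0.00399). By class, 2 of 5 tested leukocyte markers were higher and 1 lower, 2 of 3 folliculostellate or stem markers were higher, 1 of 3 fibroblast markers was higher and 1 lower, and 2 of 3 neuronal markers were lower. Further, 1 of 2 corticotroph, 1 of 3 gonadotroph and 1 of 3 thyrotroph markers were higher (Cga in both of the last), 1 of 3 epithelial markers was lower, and 0 of 1 erythroid and 0 of 3 glial markers passed the edgeR test. No endothelial marker had counts enough for testing. Cd3e, the most abundant tested leukocyte marker, stood at 86.8 ± 8.59 CPM in control and 94.0 ± 5.64 CPM in shFTO (edgeR adjusted p = 0.342). The erythroid gene Hba-a2 stood at 684 ± 9.54 and 630 ± 16.6 CPM (edgeR adjusted p = 0.202). The calls of Pomc, Cga, Anxa1, Lyz2, Pdgfra, Nefh and Krt8 were each lost when a library was left out, with Lyz2 reaching an edgeR adjusted p of 0.228 and Pdgfra 0.0543 without shFTO replicate 1, and Pomc 0.187, Cga 0.0759, Anxa1 0.143, Nefh 0.0771 and Krt8 0.206 without shFTO replicate 2.

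The 11969 m6A peaks lay in 7219 genes, of which 4391 had 1 peak, 1704 had 2 and 1124 had 3 or more, with 11 in Ahnak, a gene of a very large scaffold protein. Coding sequence held 6786 peaks (56.7%, 95% exact interval 55.8 to 57.6) and 3′ untranslated regions 4266 (35.6%, 34.8 to 36.5), in the authors' annotation. Introns held 307 (2.56%), 5′ untranslated regions 407 (3.4%) and other exons 203 (1.7%). The median peak was 448 bases wide. The median ratio was 2.76 ± 0.014 in control and 2.78 ± 0.054 in shFTO (SD, n = 2). How the ratios were scaled between libraries is not known, so these medians cannot show whether m6A changed overall. List peaks with high ratios included those of Wtap, in an intron on chromosome 1 from 47958549 to 47959291 (ratio 7.02 ± 0.0083 in control and 5.93 ± 0.229 in shFTO), and of Myc, in the coding sequence on chromosome 7 from 102590442 to 102591041 (6.52 ± 0.0551 and 5.96 ± 0.453). Neither passed the limma test (unadjusted p = 0.0688 and 0.293). No peak was listed for Fto, Alkbh5, Mettl3, Gh1 or Pou1f1.

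In ratios of unknown scaling, which may hide a shift common to all peaks, 94.2% of peaks lay within 1.5-fold between genotypes, and none passed a test. The peaks named had the smallest p in each direction among genes with an established symbol, and their values are those of peaks that did not pass. In Adsl, a purine synthesis gene, an intronic peak on chromosome 7 from 122162660 to 122162780 had a ratio of 0.660 ± 0.0095 in control and 2.44 ± 0.0524 in shFTO (SD, n = 2; limma log2 fold change 1.89 ± 0.15, adjusted p = 0.514). Coding peaks of Rai1 (chromosome 10, 46565421 to 46565515), Pde1c (chromosome 4, 86360314 to 86360414), Tbxa2r (chromosome 7, 11254747 to 11254897) and Irak3 (chromosome 7, 64925048 to 64925227) had limma log2 fold changes of 2.76, 1.73, 1.40 and 1.42 (adjusted p = 0.616). A coding peak of Cdk11b, a kinase gene, on chromosome 5 from 173065102 to 173065225 had a ratio of 8.001 ± 0.0049 in control and 3.15 ± 0.0838 in shFTO (limma log2 fold change −1.35 ± 0.099, adjusted p = 0.514). Ank2, the gene of a membrane scaffold protein, had 3 such peaks on chromosome 2, from 231247155 to 231247604 and from 231249097 to 231249546 in coding sequence and from 231250093 to 231250791 in an intron (limma log2 fold changes −1.69, −1.62 and −1.56, adjusted p = 0.616). A coding peak of Tex15 on chromosome 16 from 62326188 to 62326787 had a value of −0.98 (limma adjusted p = 0.631). The RNA of Adsl, Rai1, Pde1c, Irak3, Cdk11b, Ank2 and Tex15 did not pass the edgeR test, while that of Tbxa2r fell (−1.04 ± 0.20, edgeR adjusted p = 0.00266).

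The authors' deposited table gives a p-value under 0.05 to 0 peaks, its smallest being 0.333. The genotypes did not overlap at 4739 peaks, 39.6% against 33.33% by chance, with 2497 higher and 2242 lower in shFTO. Of these, 75 were at least 2-fold higher and 53 at least 2-fold lower in the authors' deposited table. With limma 0 peaks had an adjusted p under 0.05 (smallest 0.0778) and 843 an unadjusted p under 0.05 (7.04%). The 2 splits that mix the genotypes gave 3731 and 3499 peaks without overlap and 517 and 477 at an unadjusted limma p under 0.05. Since limma recovered 17% of simulated 2-fold changes past the adjusted threshold, single changes of that size were mostly not detectable there. At an unadjusted p under 0.05 it recovered 94% of them, beside 6.33% of the unchanged simulated peaks. The 7.04% observed lay near that share of unchanged simulated peaks, but the 843 peaks exceeded the 517 and 477 of the mixed splits. The simulation took the spread measured between each peak's own replicates as its true spread. Its shares, including the 17% recovered, may therefore differ from those of real peaks. It cannot show whether the observed share exceeds that of unchanged peaks. In the mixed splits a genotype difference would enlarge the spread, so they cannot decide this either.

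Genes with an m6A peak were lower in shFTO input than genes without one. The median log2 fold change was −0.04 over 7141 genes with a peak and 0.06 over 5902 without, and the difference matched on mean expression was −0.0924, below the 95% range of permuted labels (−0.0140 to 0.0140, permutation p = 1e-04, two-sided, the smallest that 10000 permutations can give). With a peak, 15.0% of genes fell and 7.94% rose, and without a peak 7.84% fell and 12.9% rose. The share that fell was 12.8% with 1 peak, 17.1% with 2, 18.4% with 3 and 23.2% with 4 or more, and the shares that rose were 8.67%, 6.79%, 7.32% and 6.14%. These shares are not matched: the median log2 fold change was −0.024 with 1 peak and −0.065, −0.060 and −0.071 with 2, 3 and 4 or more, while the median log2 CPM went from 5.02 to 5.96 and the median genomic span from 22.2 to 62.4 kb between 1 peak and 4 or more. Chga, Trhr and Cacna1g, each with peaks, are among the genes that fell, although Myc, Mycn and Wtap, also with peaks, rose. Genes are not independent replicates, so the permutation p describes these genes in these libraries. Matching on genomic span as well gave −0.0807, and without shFTO replicate 1 the difference was −0.0766.

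**Figure D3:**
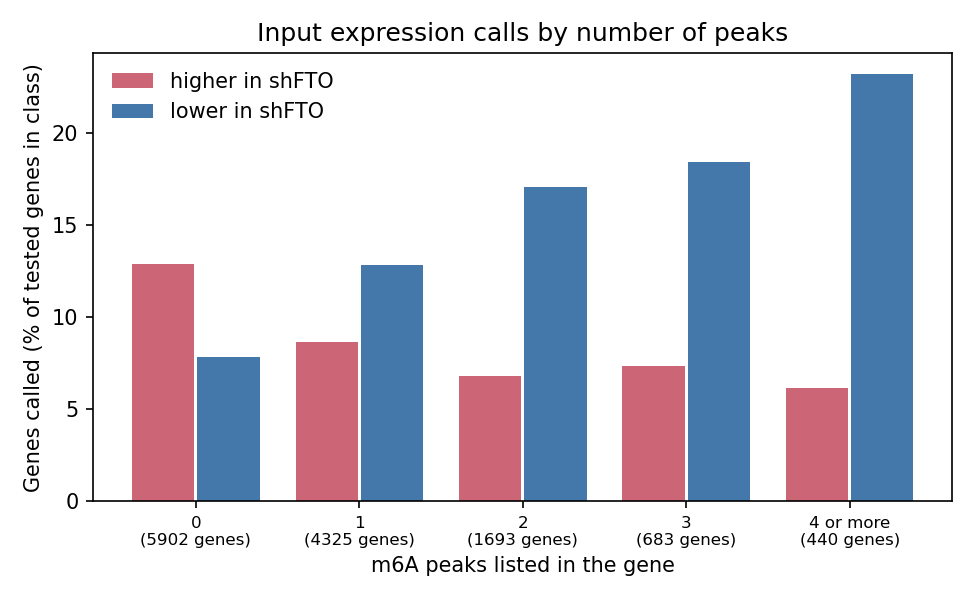
Share of tested genes (percent) called higher or lower in shFTO input by edgeR, by the number of m6A peaks listed in the gene, with the number of genes under each class. The share called lower is 7.84% without a peak and 23.2% with 4 or more.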

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

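Limits shared by these results are the pairs of replicates, of unknown origin, and the reading of the count columns as input. Tests of peaks other than the deposited p-value, list tests without a library and matching on genomic span were chosen after the data were examined. For the expression change, shFTO against control input, the replicate block gave 4767 genes (2284 genes higher in shFTO input and 2483 genes lower in shFTO input), including all 2862. The labels do not say that the numbers pair the samples, so this count is given only here. The deviations of the libraries numbered 1 in the 2 genotypes correlated at 0.309 over 9915 genes, so an effect shared by replicate number remains possible. A minimum fold of 1.5 (glmTreat) gave 129, with 45 higher and 84 lower. Without 1 library the counts ran from 1430 (without shFTO replicate 1) to 3835 (without control replicate 1), with 605 to 1739 higher and 825 to 2096 lower. Of the 2862 calls, 1367 were kept without shFTO replicate 1, 1581 without shFTO replicate 2 and 2197 by DESeq2. The number of gene lists, input expression, past camera was 0 with an estimated correlation, 7 by fry, 12 without a count filter and 9 to 12 without 1 library. Of 1390 values of 116 named genes under an alternative, 1254 kept the call, 132 lost it (79 under the minimum fold, 43 without a library) and 0 of the called changed sign. Of 161 list values 132 kept the call, 19 lost it and 10 gained it. Peaks past a limma adjusted p of 0.05 numbered 0 under each alternative, with 742 to 843 at an unadjusted p under 0.05. With a ratio of at least 1 in every RNA sample there were 2372 peaks higher in shFTO without overlap and 2172 peaks lower in shFTO without overlap. Of the peaks above the median ratio 56.9% lay in coding sequence. The difference for genes with peaks ran from −0.0766 to −0.114. The fits that need gene counts of immunoprecipitates, the motif search and the overlap minimum were not run. The cause of these differences was not tested.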

Other observations

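The tests of peak shares by list, of peak direction against RNA and of the mitochondrial share, the cilium list and the use of a bootstrap interval beside the span-matched lists were chosen only after the results were seen. Peaks were most frequent in immediate early genes (26 of 28, 92.9%, Fisher adjusted p = 0.00025) and in transcripts widely reported to carry m6A (28 of 31, 90.3%, Fisher adjusted p = 0.00025), against 54.7% of other tested genes. They were least frequent in ribosomal protein genes (3 of 29, 10.3%, Fisher adjusted p = 3.1e-05) and in glycolysis and hypoxia genes (7 of 25, Fisher adjusted p = 0.048, against 54.8%). These shares were not matched on expression, genomic span or transcript length. The immediate early list and the list of transcripts reported to carry m6A share members such as Myc and Jun, so their results are not separate. The peak with the smallest limma p lay in the coding sequence of LOC103690317 on chromosome 7 from 140207180 to 140207294, with ratios of 12.04 ± 2.996 in control and 0.264 ± 0.0030 in shFTO (limma adjusted p = 0.0778), while its RNA rose (log2 fold change 3.15 ± 0.19, edgeR adjusted p = 9.73e-07). Of 6 mitochondrial peaks, 5 had lower ratios without overlap, such as that of Mt-nd6 (5.38 ± 0.140 and 3.89 ± 0.283, limma adjusted p = 0.664), while the RNA of these genes rose. For these peaks and that of LOC103690317, higher input RNA can itself lower the ratio, so no change in m6A can be read from them. Vim, a mesenchymal filament gene, had 2 counts in control and 65 in shFTO, a ratio of 31.9 (8.48 to 269), and Tmsb10 had 2 and 46, a ratio of 22.6 (5.9 to 192). The low control counts leave the size of both open, and for Vim the log2 fold change was 8.03 without control replicate 1. Whether reads of Vim and Tmsb10 were fully counted is not known, so the rises may not be changes in RNA.

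Genes with an m6A peak were lower in shFTO than genes without one. A trend with genomic span is argued against as the whole cause. Matching also on span left a difference of −0.0807, against −0.0926 for the same genes matched on expression only. Genomic span includes introns and transcript length was not matched, so a trend with transcript length remains open. A single library is argued against as well, since the value nearest 0 was −0.0766, without shFTO replicate 1, outside the permuted range. The peaks were listed from the same RNA samples as the counts. Whether input reads shared by both add to the difference was not tested. A candidate explanation is that transcripts whose peak ratio rose lost RNA: genes with higher peaks only differed from genes with lower peaks only by −0.0555 (permuted −0.0238 to 0.0248). This cannot be told apart from the input counts entering both values, as the correlation of peak and RNA change (−0.0728) lay nearer 0 than those between replicates (−0.173 in control and −0.26 in shFTO).

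Mitochondrial and ribosomal protein genes were higher and ion channel genes lower. Under total-count scaling the larger mitochondrial share would move all other genes by −0.0244 (log2), small beside the ion channel median of −0.34. A change in share of this size could not have given more, and the fold changes were TMM-scaled, so this decides nothing about the pattern. For ion channel genes a trend with genomic span is argued against. Their median lay at percentile 0 of lists matched on expression and span (−0.16 to 0.096), and its bootstrap interval was −0.53 to −0.18. Transcript length was not matched for this list or the following ones, so a trend with transcript length remains open for all of them. The same comparison leaves the span trend open for the cAMP/PKA list (median −0.18, inside its matched range of −0.181 to 0.0673, percentile 2.97). The span trend is also open for interferon genes, whose median of 0.226 lay above the matched range of −0.124 to 0.165 at percentile 99.76. Their bootstrap interval of 0.118 to 0.402 reached into that range. For cholesterol synthesis genes the comparison argues against a span trend (bootstrap from 0.182, matched range to 0.117). For ribosomal protein genes the median of 0.20 lay at percentile 98.5, above the matched range of 0.046 to 0.199, but its bootstrap interval (0.18 to 0.27) reaches into that range. The span trend cannot be told apart from a change in these genes, and the bootstrap rule, added after the values were seen, turned this from excluded to open.

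Dnai1, an axonemal gene, was among the highest in shFTO, and a hypothesis is that motile cilium genes may be higher as a set: their median log2 fold change was 0.36 over 29 tested genes (camera across genes with the preset correlation, unadjusted p = 0.000158). By edgeR 7 of them rose and 0 fell, with Ropn1l at 1.22 ± 0.18 and Enkur at 1.04 ± 0.17. Of the 7, Rsph9 lost its call without shFTO replicate 1 (edgeR adjusted p = 0.189), Tekt1 and Ttc25 lost theirs without shFTO replicate 2 (0.178 and 0.0735), and DESeq2 did not call Dnai1 (adjusted p = 0.194, in a range of 9.48e-14 to 0.339 over 12 alternatives). With an estimated correlation camera p was 0.188, so the call rests on the preset correlation. No technical explanation was tested for this pattern, and the list was written after the highest genes were seen.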
